A study of Mus musculus with 24 samples.

How the data were processed

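Total RNA from bone marrow cells cultured with Flt3 ligand at 100 ng/ml until day 9 was hybridised in 1 colour (Cy3) to Agilent mouse arrays, per the labels' protocols. Cells of 4 genotypes on a C57BL/6 background (WT, Irf5-KO, Lyn-KO and DKO), unstimulated or with 150 nM CpG-B for 6 h, made 8 groups with 3 arrays each, 24 arrays in all. The scanner output of each array was read with Feature Extraction 10.7.3.1, per the file headers. Its processed signal is an intensity that was background-subtracted and corrected for spatial trends on the array, with no scaling between arrays, per the file headers. The deposited series table holds log2 values, which by comparison with the scanner output were shifted to the 75th percentile of each array and then centred on the median of each probe. Differences between arrays in that table lay within 0.00238 of those computed here for 95% of the values, over 13396 probes with a signal of at least 200.

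The processed signal of each spot was taken to log2, and the 75th percentile of the array was subtracted. Of 62976 spots per array, 59305 were not controls and held 55681 probes, and 4351 spot values that the scanner software had marked as not uniform or as outliers were left out. Spots of a probe were averaged. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 26642 probes. Names came from matching the accession of each probe to a gene table of the assembly GRCm38.p6, which named 26762 probes, while 28919 stayed without a name, 1628 of them with an accession of RefSeq form. The files annotate the probes to another build (mm9), so no coordinates are printed, and the gene table served for names and for which genes lie near each other. A gene with several probes was represented by the probe with the highest mean, which applied to 6478 of the 20189 features tested, of which 12643 were named genes and 7546 were not. There were 18 missing values. Between 41.0% and 53.8% of the spots of an array were well above background, and the number of arrays limits the precision.

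All 24 arrays were fitted with 1 mean per group in limma 3.58.1 (R 4.3.3, with the package data.table in version 1.17.8), so that the 8 groups shared the estimate of the spread of each feature. The 19 contrasts were the CpG-B response in each genotype, the genotype comparisons without and with CpG-B, the differences of the CpG-B response between each mutant and WT, and the Irf5 dependence of the Lyn-KO effect. A feature was called at a Benjamini-Hochberg adjusted p of 0.05 within a contrast (limma, 2-sided), and counts with at least a 2-fold change are given beside it. The 25 gene lists of pathways and cell types were tested with camera at a preset correlation between genes of 0.01, and beside it with an estimated correlation, for lists with at least 5 measured genes, adjusted over the lists within a contrast. Genes could be named in the text if they were among the 12 called genes with the largest positive or the 12 with the largest negative change of a contrast, had a symbol, were well above background on all 3 arrays of the brighter group and did not overlap between the groups, or if they were in a fixed list or were Irf5 or Lyn. The contrasts, tests, lists, naming rule and alternatives were chosen before the data were examined. The genes that the text singles out were picked from within that rule after their values were seen, except that Fcmr is also given for Lyn-KO against WT with CpG-B, where the rule does not reach it. Most genes whose call ended on leaving out 1 array were passed over in that choice, so the named genes are more stable than the rest: 2 of 171 called gene results in the text lost their call in this way, against 688 of 4491 (15.3%) among all that the naming rule or the lists allow.

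For a gene that no array of a group measured, that group was set to the higher of its own value and the lowest signal well above background on each array, and the fold is a lower bound. Overlaps of calls between contrasts are given beside the number for independent lists. Genes within 20 Mb of Irf5 or Lyn, without the targeted gene itself, were compared with all others by Fisher's exact test.

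The alternatives were quantile normalisation, normexp background correction with an offset of 50 followed by quantile normalisation, scaling to the median of probes detected on all arrays, no filter on dim probes, only probes well above background on all arrays (15783 features), every probe tested on its own, the replicate number as a block, only the groups of the contrast in the fit, the deposited series table, a variance prior with trend and robust estimation, windows of 10 and 40 Mb around the targeted genes, and leaving out each array in turn. Normexp used the median signal of the spots because the files hold no mean signal. The unfiltered alternative and the series table used features with no missing value. Each of the 3 slides held 1 array of every group, the replicate number was the slide, and every group lay at the same position on each slide, so position and group cannot be told apart.

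The fit was tested on simulated data with known changes in 200 genes among the 20189 features. For Irf5-KO against WT with CpG-B it recovered 65.7%, 79.1% and 98.5% of the genes changed by 1.5-fold, 2-fold and 4-fold, and called 7 unchanged features. For DKO against Lyn-KO without stimulation it recovered 59.7%, 80.6% and 98.5% and called 8. For the Irf5 dependence of the Lyn-KO effect with CpG-B it recovered 41.8%, 61.2% and 90.9% and called 4. A list of 20 genes shifted by 0.5 on the log2 scale was called in each of the 3 simulations and none of the other lists was. The simulated genes varied independently of each other. This check therefore cannot tell how the list test behaves for genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The cytokine gene Il12b had no matching probe and was not analysed here. Some genes measured are not reported here.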

Results

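Gene expression was measured with 1-colour Agilent mouse arrays in dendritic cells grown from mouse bone marrow with the growth factor Flt3 ligand, a culture that yields plasmacytoid and conventional dendritic cells. The cells came from wild type (WT) animals, from animals lacking Irf5, a transcription factor of Toll-like receptor signalling, from animals lacking Lyn, a Src-family tyrosine kinase, and from animals lacking both (DKO). At day 9 of culture, cells of each genotype were left unstimulated or received CpG-B, a synthetic DNA that is sensed by Toll-like receptor 9, at 150 nM for 6 h. This gave 8 groups of 3 arrays, 24 arrays in all. The comparisons ask how CpG-B changes the transcriptome in each genotype, what loss of Irf5 or Lyn changes with and without CpG-B, and whether the effect of losing Lyn depends on Irf5.

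Between 24332 and 31879 of the 59305 non-control spots of an array were well above background, which was 41.0% to 53.8%, and no spot was saturated. The 75th percentile of the processed signal lay between 303 and 568. After filtering, 20189 features were tested, of which 12643 had a gene symbol. Replicate arrays of a group correlated at 0.9909 to 0.9959 (Pearson, across features, which are not independent replicates), and the median residual standard deviation of a feature was 0.134 on the log2 scale. Principal component 1 held 73.7% of the variance and separated CpG-B from unstimulated arrays, component 2, which parted all Lyn-KO and DKO arrays from all WT and Irf5-KO arrays, held 9.64% and component 3 held 4.91%. Only 3 arrays per group limit the precision, and the p-values measure the spread between the cultures that the labels call biological replicates. Values after a gene are log2 fold changes ± the standard error of the limma fit with 3 arrays per group, and every gene given such a value passed an adjusted p of 0.05 unless its p is printed. Counts for a gene list are those over all genes tested, and the count adjusted over the list alone follows where it differed. The 3 slides each held 1 array of every group, so list medians are also given within slides 1, 2 and 3, in square brackets, where 1 array per group allows no test.

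**Figure D1:**
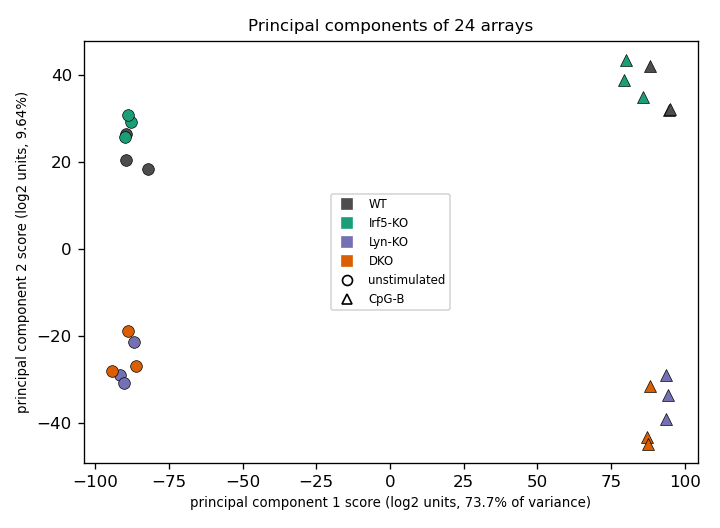
Principal components 1 and 2 of the 20189 tested features for the 24 arrays, in log2 units of the scores, with colour for the genotype and shape for the treatment (circles unstimulated, triangles CpG-B). Component 1, with 73.7% of the variance, parts the 12 CpG-B arrays from the 12 unstimulated ones.

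The signals of the targeted genes were examined before any other result. Lyn was well above background on all 24 arrays and fell in the arrays labelled Lyn-KO against WT (-1.83 ± 0.09 unstimulated and -2.44 ± 0.09 with CpG-B). It was lower in the arrays labelled DKO than in Irf5-KO arrays (-1.96 ± 0.09 and -2.58 ± 0.09). With CpG-B, Lyn was also lower in Irf5-KO than in WT arrays (-0.73 ± 0.09) and lower in DKO than in Lyn-KO arrays (-0.87 ± 0.09), and in WT cells CpG-B raised it by 1.24 ± 0.09. Irf5, represented by 1 probe, was not called lower in arrays labelled Irf5-KO than in WT, or in DKO than in Lyn-KO arrays, and with CpG-B it was called higher in both. The change in Irf5-KO against WT arrays was -0.30 ± 0.09 unstimulated (adjusted p = 0.161) and 0.64 ± 0.09 with CpG-B (adjusted p = 2.8e-05). In DKO against Lyn-KO arrays it was -0.29 ± 0.09 (adjusted p = 0.347) and 0.76 ± 0.09. Whether this probe lies inside the deleted part of the gene is not given in the sources used here, so its signal checks nothing, and Irf5-KO and DKO below mean the arrays labelled so.

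**Figure D2:**
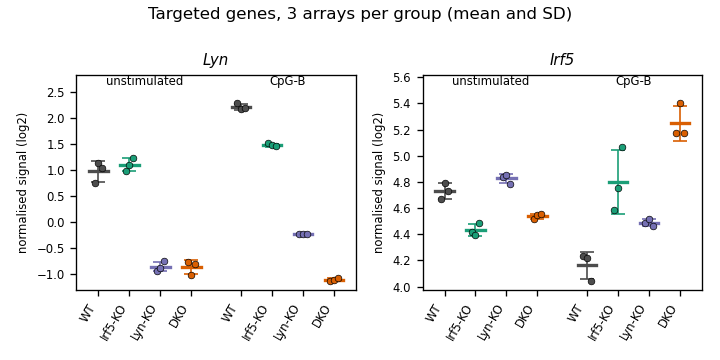
Normalised log2 signal of Lyn and of Irf5 on each of the 24 arrays (points) with the mean (horizontal lines) and standard deviation (whiskers) of each group of 3. Lyn lies lower in the arrays labelled Lyn-KO and DKO than in the other genotypes of the same treatment, while Irf5 is not lower in the arrays labelled Irf5-KO and DKO with CpG-B.

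In WT cells CpG-B raised interferon, cytokine and maturation genes. Il6 and Tnf, which encode inflammatory cytokines, rose by 7.25 ± 0.12 and 3.01 ± 0.17, and Il10, an anti-inflammatory cytokine, by 4.45 ± 0.19. The interferon gene Ifnb1 rose by 4.72 ± 0.25, the interferon-induced antiviral genes Rsad2 and Ifit1 by 6.64 ± 0.28 and 5.76 ± 0.26, and Irf7, a transcription factor of interferon production, by 5.90 ± 0.20. The costimulatory receptor gene Cd40 rose by 4.74 ± 0.08 and Ccr7, the receptor that guides mature dendritic cells to lymph nodes, by 3.23 ± 0.12. Among single genes, Saa3, an acute phase protein, rose by 8.96 ± 0.52, Vgf was at least 450-fold higher, and Amz1 (-6.93 ± 0.13) and Ppfia4 (-6.29 ± 0.13) fell. A fold given as a lower bound sets the brighter group against the lowest signal called well above background on each array of a group in which no array measured the gene. Such a bound holds for the processing used here only, and a change after normexp correction that is given beside it is smaller than the bound.

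By list, 13 of 14 type I and III interferon genes rose (median 4.74, 4.67 at the bound [4.53, 5.11, 4.58], adjusted p = 4.1e-07, or 0.147 with an estimated correlation). So did 61 of 61 interferon-stimulated genes (median 4.22, 4.20 at the bound [4.10, 4.30, 4.41], adjusted p = 8.01e-28, or 0.0906 with an estimated correlation). The second median after a list has the genes that were below background in a group at their bound. Of the inflammatory cytokines, 18 of 19 rose (median 4.20, 4.0 at the bound [4.35, 4.30, 3.91], adjusted p = 8.26e-10, or 0.00297 with an estimated correlation). Chemokine genes were 16 higher and 2 lower of 19 (median 2.41 [2.51, 2.25, 2.31], adjusted p = 9.35e-05, or 0.239 with an estimated correlation). Among them were Ccl5 at 2.21 ± 0.15 and Cxcl10 at 4.81 ± 0.31. The NF-kB targets and feedback regulators were 38 higher and 2 lower of 43 (median 1.75 [1.94, 1.82, 1.73], adjusted p = 2.69e-13, or 0.0648 with an estimated correlation). They included Nfkbia and Tnfaip3, inhibitors of that pathway, at 2.03 ± 0.08 and 3.06 ± 0.08. Costimulation and migration genes were 21 higher and 3 lower of 25 (median 2.22 [2.19, 2.31, 2.16], adjusted p = 1e-07, or 0.0325 with an estimated correlation). Markers of type 1 conventional dendritic cells were 2 higher and 15 lower of 17 (median -2.10 [-2.12, -1.94, -2.12], adjusted p = 9.35e-05, or 0.147 with an estimated correlation), with a median of -1.12 with only probes detected on all arrays. Tlr11 was at least 23.5-fold lower (-2.94 on the log2 scale after normexp correction) and Irf8 fell (-0.76 ± 0.09), whereas the transcription factor Batf3 rose by 2.64 ± 0.15. Cholesterol synthesis genes were 16 higher and 5 lower of 23 (median 0.76 [0.75, 0.73, 0.83], adjusted p = 0.00266, or 0.42 with an estimated correlation). Hmgcs1, which feeds the mevalonate pathway, rose by 1.90 ± 0.09.

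limma called 13824 features in WT cells at an adjusted p of 0.05, 6306 higher and 7518 lower, and 2767 and 2803 of them by at least 2-fold. Here and below, counts of at least 2-fold changes depend on the processing, and over the 19 contrasts 15 of them moved by more than 1.5 times after normexp correction. The response was of like extent in the other genotypes: 13499 features in Irf5-KO, 13910 in Lyn-KO and 14235 in DKO cells. Across the 4 genotypes, 4593 features rose and 5478 fell in all of them, against 227 and 343 for independent lists, and 775 rose in 1 genotype and fell in another. The unstimulated and CpG-B arrays differ between genotypes, so these are 4 separate tests with no array in common. All 61 interferon-stimulated genes rose in Irf5-KO cells (median 4.66, 4.55 at the bound [4.59, 4.45, 4.81], adjusted p = 2.87e-30, or 0.0566 with an estimated correlation). They all rose in Lyn-KO cells too (median 4.72, 4.66 at the bound [4.61, 4.81, 4.65], adjusted p = 2.27e-28, or 0.0856 with an estimated correlation), and in DKO cells (median 4.75, 4.73 at the bound [4.69, 4.22, 4.90], adjusted p = 1.57e-27, or 0.0933 with an estimated correlation). The median change of the interferon genes was 3.91, 3.74 at the bound in Irf5-KO, 7.85, 7.45 at the bound in Lyn-KO and 6.55, 6.13 at the bound in DKO cells, with 13 of 14 called higher in each and adjusted p of 3.12e-06, 4.6e-09 and 4.03e-08 (0.156, 0.0892 and 0.104 with an estimated correlation). After normexp correction that of Irf5-KO was 2.24. With the slide as a block limma called 14182, 13868, 14264 and 14559 features in the 4 genotypes.

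Without stimulation, few features differed between arrays labelled Irf5-KO and WT. Asns, which makes asparagine, was higher by 1.13 ± 0.11 and Trib3, a gene of the integrated stress response, by 0.91 ± 0.10. The chemokine gene Ccl5 was lower, at -0.96 ± 0.15, and so was the interferon-induced gene Ifit2, at -1.25 ± 0.25, though not called without replicate 1 or without replicate 3 of the Irf5-KO arrays (-1.13 and -1.22), and at -0.82 without replicate 1 of the WT arrays and -0.80 after normexp correction. Il10 was higher by 1.25 ± 0.19. Hsd11b1, which activates glucocorticoids, was lower, at -1.18 ± 0.17, and Fam89a was at least 4.26-fold lower. Syt10, a calcium sensor of vesicle release, was at least 10.6-fold higher, a call that ended after normexp correction (2.13 on the log2 scale). The same correction gave -0.66 for Hsd11b1 and -0.95 for Fam89a. Arf5, which lies within 10 Mb of Irf5, was lower, at -0.93 ± 0.12.

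Of the endoplasmic reticulum and oxidative stress genes, 5 of 25 (8 higher and 1 lower adjusted over the list alone) were higher (median 0.18, 0.12 at the bound [0.21, 0.17, 0.13], adjusted p = 7.51e-12, or 0.00467 with an estimated correlation). Of the interferon-stimulated genes, 4 of 61 (0 higher and 32 lower adjusted over the list alone) were lower (median -0.33 [-0.61, -0.29, -0.12], adjusted p = 1.66e-20, or 0.185 with an estimated correlation). B cell markers were 1 higher and 0 lower of 14 (5 higher and 0 lower adjusted over the list alone, median 0.22 [0.51, 0.45, -0.02], adjusted p = 0.00111, or 0.185 with an estimated correlation), a direction that slide 3 did not share. Their median was 0.13 without replicate 1 of the Irf5-KO or replicate 2 of the WT arrays, and 0.33 without replicate 3 of the Irf5-KO arrays or with only probes detected on all arrays. limma called 149 features, 64 higher and 85 lower (181 features with the slide as a block). With only these 6 arrays fitted, 1 feature was called and the genes named here other than Syt10 lost their calls. The count was 74 without the filter on dim probes, 53 without replicate 1 of the unstimulated WT arrays, and 77, 46 and 97 without replicate 1, 2 or 3 of the unstimulated Irf5-KO arrays.

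Unstimulated Lyn-KO arrays held less transcript of B lineage genes than WT. Pou2af1, a B cell transcriptional coactivator, was lower, at -4.70 ± 0.37, Ms4a1, a surface marker of B cells, at -3.47 ± 0.19, Mzb1, a chaperone of antibody-secreting cells, at -3.88 ± 0.33, Jchain, which joins secreted antibody, at -3.46 ± 0.30 and Fcmr, an IgM receptor, at -4.43 ± 0.26. Blnk, an adaptor of B cell receptor signalling, was at 0.18 ± 0.06 (adjusted p = 0.131). The interferon-induced genes Ifit3, Ifit2 and Isg15 were lower, at -2.29 ± 0.30, -1.96 ± 0.25 and -1.05 ± 0.21. Ctsk, a cysteine protease, was higher by 1.79 ± 0.37, and Syt10 was at least 23.2-fold higher. Il10 was at least 3.51-fold lower. After normexp correction the changes were -1.22 for Ifit2, 3.1 for Syt10 and -1.01 for Il10 on the log2 scale.

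B cell markers were 0 higher and 7 lower of 14 (2 higher and 7 lower adjusted over the list alone, median -1.01 [-1.23, -0.70, -1.20], adjusted p = 1.82e-10, or 0.0248 with an estimated correlation). Their median was -0.46 after normexp correction and -0.56 with every probe tested on its own. Interferon-stimulated genes were 1 higher and 30 lower of 61 (2 higher and 46 lower adjusted over the list alone, median -0.48 [-0.63, -0.49, -0.29], adjusted p = 4.03e-30, or 0.0958 with an estimated correlation). Plasmacytoid dendritic cell markers were 5 higher and 0 lower of 18 (12 higher and 1 lower adjusted over the list alone, median 0.31 [0.31, 0.27, 0.28], adjusted p = 1.37e-06, or 0.163 with an estimated correlation). limma called 925 features, 369 higher and 556 lower, of which 351 by at least 2-fold (1126 features with the slide as a block). With only these 6 arrays fitted, 321 features were called, and Ifit2, Ifit3 and Isg15 were not among them. The count was 608 without the filter on dim probes and 593 without replicate 3 of the unstimulated Lyn-KO arrays.

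DKO arrays without stimulation again held less B lineage transcript than WT, and also less of genes of neutrophil precursors. Pou2af1 and Ms4a1 were lower, at -4.04 ± 0.37 and -3.29 ± 0.19. Camp, an antimicrobial peptide of neutrophil granules, was lower, at -1.44 ± 0.22, and Ifit3 at -2.40 ± 0.30. Ctsk was higher by 2.32 ± 0.37, Trib3 by 1.13 ± 0.10 and Asns by 1.10 ± 0.11, and Syt10 was at least 13.9-fold higher. B cell markers were 0 higher and 9 lower of 14 (2 higher and 9 lower adjusted over the list alone, median -1.37, -1.10 at the bound [-1.53, -1.01, -1.47], adjusted p = 1.23e-11, or 0.0154 with an estimated correlation). Neutrophil and granulocyte precursor markers were 0 higher and 7 lower of 17 (0 higher and 11 lower adjusted over the list alone, median -0.92, -0.66 at the bound [-0.42, -1.13, -1.49], adjusted p = 3.79e-07, or 0.129 with an estimated correlation). Normexp correction gave medians of -0.72 for the B cell and -0.58 for the neutrophil list, and 2.43 for Syt10. Interferon-stimulated genes were 1 higher and 23 lower of 61 (3 higher and 36 lower adjusted over the list alone, median -0.37 [-0.68, -0.11, -0.34], adjusted p = 1.47e-17, or 0.189 with an estimated correlation), with a median of -0.25 without replicate 1 of the WT arrays. limma called 1370 features, 639 higher and 731 lower, of which 470 by at least 2-fold (1709 with the slide as a block). With only these 6 arrays fitted, 530 features were called, without Ifit3. The count was 900 without the filter on dim probes and 872 and 886 without replicate 1 of the unstimulated WT or DKO arrays. Within a treatment, the comparisons of Irf5-KO, Lyn-KO and DKO with WT all used the same 3 WT arrays. A like change in several of them, such as that of Syt10 or the interferon-stimulated genes, is therefore not an independent repeat.

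Against Irf5-KO, unstimulated DKO arrays held less of the B lineage transcripts that were lower in Lyn-KO against WT: Ms4a1 was lower, at -4.03 ± 0.19, and Pou2af1 at -4.72 ± 0.37. Il10 was at least 6.49-fold lower, and Mcpt8, a basophil protease, was higher by 1.42 ± 0.26. B cell markers were 0 higher and 8 lower of 14 (median -1.31, -0.85 at the bound [-2.01, -1.36, -1.13], adjusted p = 3.52e-15, or 0.00384 with an estimated correlation). Their median was -0.64 after normexp correction and -0.79 with every probe tested on its own, and Il10 was at -1.81 after normexp correction. Plasmacytoid dendritic cell markers were 7 higher and 0 lower of 18 (10 higher and 1 lower adjusted over the list alone, median 0.33 [0.30, 0.47, 0.30], adjusted p = 9.55e-06, or 0.193 with an estimated correlation). limma called 1079 features, 499 higher and 580 lower (1294 with the slide as a block), and 704 without replicate 2 of the unstimulated Irf5-KO arrays. Against Lyn-KO, few genes differed: limma called 32 features, 17 higher and 15 lower. Of the 20189 features tested, 1349 had an unadjusted p below 0.05 (limma), where a share of 0.05 would with no difference. The higher genes again included Asns (1.27 ± 0.11), Trib3 (1.17 ± 0.10) and Chac1, of the same stress response (1.10 ± 0.16). The lower genes included Arf5 (-0.88 ± 0.12) and Fam89a (at least 3.8-fold lower, -1.10 on the log2 scale after normexp correction). Of the stress genes, 3 of 25 (7 higher and 0 lower adjusted over the list alone) were higher (median 0.15 [0.20, 0.11, 0.14], adjusted p = 3.56e-09, or 0.00693 with an estimated correlation). Of the mast cell, basophil and eosinophil markers, 1 of 11 (4 higher and 0 lower adjusted over the list alone) were higher (median 0.81 [0.41, 0.48, 0.70], adjusted p = 4.26e-07, or 0.00693 with an estimated correlation). The median of the stress genes was 0.08 without replicate 1 of the DKO arrays. That of the mast cell list was 0.52 without replicate 3 of the Lyn-KO arrays. It was 0.53 with every probe tested on its own and 0.30 after normexp correction. With only these 6 arrays fitted, 1 feature was called and the genes named here lost their calls. The count was 21 without the filter on dim probes or with probes detected on all arrays only, 51 with quantile normalisation, and 20 and 51 without replicate 3 of the Lyn-KO and of the DKO arrays.

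**Figure D3:**
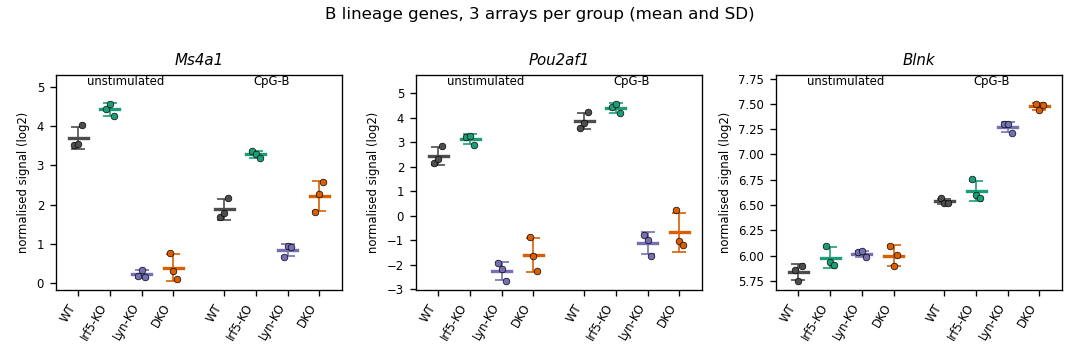
Normalised log2 signal of the B lineage genes Ms4a1, Pou2af1 and Blnk on each of the 24 arrays (points) with the mean (horizontal lines) and standard deviation (whiskers) of each group of 3. Unstimulated Lyn-KO and DKO arrays lie below the unstimulated WT and Irf5-KO arrays for the first 2 genes, whereas for Blnk the change in Lyn-KO against WT was 0.18 ± 0.06 and was not called (adjusted p = 0.131).

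With CpG-B, arrays labelled Irf5-KO held less interferon and cytokine transcript than WT. Ifnb1 was lower, at -2.24 ± 0.25, Il6 at -0.93 ± 0.12, Tnf at -0.94 ± 0.17, Il10 at -1.10 ± 0.19, Il27, a cytokine subunit, at -2.02 ± 0.16 and Lta, lymphotoxin alpha, at -3.19 ± 0.18. Il19 was lower, at -4.83 ± 0.34, Hsd11b1 at -4.75 ± 0.17, Fam89a at -4.63 ± 0.25 and Parm1 at -3.68 ± 0.09. Il1b was higher by 1.21 ± 0.14 and the chemokine genes Cxcl2 and Ccl22 by 1.73 ± 0.35 and 1.54 ± 0.24. Slc16a3, a lactate transporter, was higher by 1.31 ± 0.11, the cholesterol synthesis genes Sqle and Hmgcs1 by 0.70 ± 0.07 and 0.70 ± 0.09, and Hmox1, a haem-degrading enzyme of oxidative stress, by 1.21 ± 0.20.

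Of the interferon genes, 11 of 14 (0 higher and 13 lower adjusted over the list alone) were lower (median -0.98 [-0.91, -1.40, -0.58], adjusted p = 1.45e-06, or 0.215 with an estimated correlation). Inflammatory cytokines were 2 higher and 11 lower of 19 (3 higher and 11 lower adjusted over the list alone, median -0.84 [-0.84, -0.76, -0.66], adjusted p = 4.18e-05, or 0.0293 with an estimated correlation), with a median of -0.46 after normexp correction. Of the interferon-stimulated genes 4 higher and 1 lower of 61 (1 higher and 1 lower adjusted over the list alone) were called, with a median of 0.01 (adjusted p = 0.778). Glycolysis genes were 14 higher and 1 lower of 22 (15 higher and 1 lower adjusted over the list alone, median 0.45 [0.45, 0.47, 0.32], adjusted p = 1.8e-07, or 0.0245 with an estimated correlation). Cholesterol synthesis genes were 18 higher and 0 lower of 23 (19 higher and 1 lower adjusted over the list alone, median 0.55 [0.55, 0.50, 0.62], adjusted p = 1.72e-09, or 0.0761 with an estimated correlation). The stress genes were 19 higher and 0 lower of 25 (19 higher and 1 lower adjusted over the list alone, median 0.44, 0.40 at the bound [0.33, 0.57, 0.28], adjusted p = 8.34e-08, or 0.0245 with an estimated correlation). Of the monocyte and macrophage markers 12 of 19 (13 higher and 0 lower adjusted over the list alone) were higher (median 0.60 [0.44, 0.68, 0.55], adjusted p = 2.9e-04, or 0.275 with an estimated correlation). Csf1r, a growth factor receptor of these cells, was higher by 0.78 ± 0.11, and plasmacytoid dendritic cell markers were 0 higher and 8 lower of 18 (1 higher and 8 lower adjusted over the list alone, median -0.11 [-0.19, -0.28, -0.14], adjusted p = 1.47e-04, or 0.275 with an estimated correlation). The median of the plasmacytoid list was -0.05 and -0.16 without replicate 1 or 3 of the WT arrays, and -0.17 and -0.06 without replicate 1 or 2 of the Irf5-KO arrays. limma called 5149 features, 2913 higher and 2236 lower, of which 769 by at least 2-fold (5729 with the slide as a block).

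With CpG-B, Lyn-KO cells held more interferon transcript than WT. Ifnb1 was higher by 2.72 ± 0.25, which was 6.59-fold, Ifna4 by 3.20 ± 0.36, Ifna5 by 3.06 ± 0.27, Ifnl3, a type III interferon, by 0.65 ± 0.12 and Ifnk by 0.74 ± 0.19. Ifnl3 lost its call with only these 6 arrays fitted, and Ifnk without replicate 3 of the WT arrays (0.56), and Ifnk was at 0.34 after normexp correction. The Ifna genes are close in sequence, so a single member of that family is not told apart here with certainty. Tnf was higher by 1.11 ± 0.17, Lta by 2.29 ± 0.18, Il1b by 1.13 ± 0.14, and the chemokine genes Xcl1, Cxcl1 and Cxcl2 by 2.63 ± 0.28, 2.07 ± 0.36 and 1.96 ± 0.35. Il6 was at 0.31 ± 0.12 (adjusted p = 0.0725) and Il10 at -0.14 ± 0.19 (adjusted p = 0.63). Of the B lineage genes named above, Pou2af1, Mzb1, Jchain and Ms4a1 were lower with CpG-B too, at -5.01 ± 0.37, -4.12 ± 0.33, -3.87 ± 0.30 and -1.04 ± 0.19, whereas Fcmr was at 0.02 ± 0.26 (adjusted p = 0.963).

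All 14 measured interferon genes were higher (median 2.80 [2.50, 2.63, 3.24], adjusted p = 2.43e-15, or 0.0649 with an estimated correlation). Interferon-stimulated genes were 1 higher and 1 lower of 61 (0 higher and 0 lower adjusted over the list alone), with a median of -0.05 (adjusted p = 0.283). They were called lower as a list only after normexp correction (median -0.12). Chemokine genes were 11 higher and 1 lower of 19 (median 0.63 [0.47, 0.54, 0.92], adjusted p = 2.61e-04, or 0.415 with an estimated correlation). Cell cycle genes were 1 higher and 23 lower of 43 (1 higher and 25 lower adjusted over the list alone, median -0.21 [-0.19, -0.16, -0.32], adjusted p = 6.42e-09, or 0.387 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at -1.0 ± 0.12. Plasmacytoid dendritic cell markers were 11 higher and 0 lower of 18 (median 0.56 [0.47, 0.48, 0.60], adjusted p = 1.17e-06, or 0.387 with an estimated correlation, and a median of 0.37 after normexp correction), with Tcf4 and Spib, transcription factors of these cells, at 0.69 ± 0.09 and 0.71 ± 0.08. B cell markers were 2 higher and 5 lower of 14 (2 higher and 6 lower adjusted over the list alone) and passed no test as a list (median -0.37, -0.17 at the bound, adjusted p = 0.169). limma called 5082 features, 2817 higher and 2265 lower, of which 877 by at least 2-fold (5796 with the slide as a block).

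**Figure D4:**
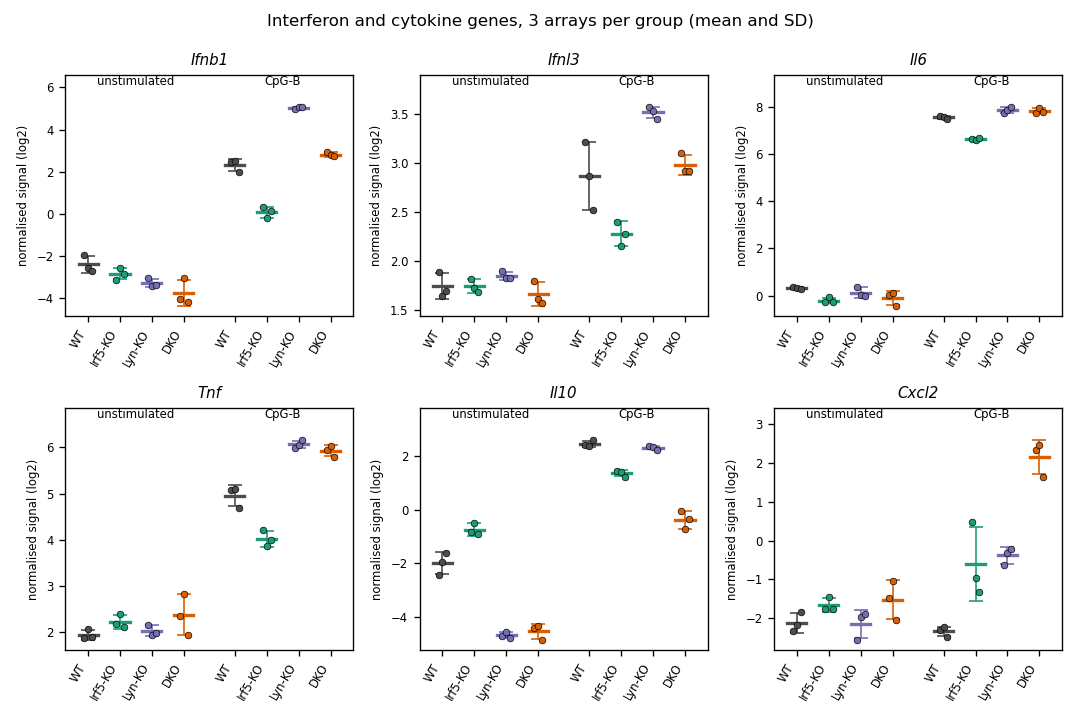
Normalised log2 signal of Ifnb1, Ifnl3, Il6, Tnf, Il10 and Cxcl2 on each of the 24 arrays (points) with the mean (horizontal lines) and standard deviation (whiskers) of each group of 3. With CpG-B the Ifnb1 signal is highest in Lyn-KO cells, 2.72 ± 0.25 above WT, and lowest in cells labelled Irf5-KO, -2.24 ± 0.25 against WT.

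DKO cells with CpG-B differed from WT by more genes than either single knockout did. Ifnb1 was at 0.49 ± 0.25 (adjusted p = 0.12) and passed the threshold only after normexp correction (0.47), while Ifna1 and Ifna4 were higher by 1.48 ± 0.15 and 1.72 ± 0.36. Cxcl1 and Cxcl2, neutrophil-attracting chemokines, were higher by 3.60 ± 0.36 and 4.48 ± 0.35, Ccl22 and Ccl17 by 3.05 ± 0.24 and 2.61 ± 0.26, and Il1b and Tnf by 1.64 ± 0.14 and 0.97 ± 0.17. Il10 was lower, at -2.84 ± 0.19 and Il27 at -1.32 ± 0.16, and Il19 was at least 80.8-fold lower. Srxn1, an antioxidant enzyme, was higher, at 3.50 ± 0.11, the cholesterol synthesis genes Sqle and Hmgcs1 at 1.26 ± 0.07 and 1.18 ± 0.09, and the replication genes Rrm2 and Mcm4 were lower, at -1.29 ± 0.12 and -1.03 ± 0.08.

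Of the interferon genes 12 of 14 were higher (median 1.53 [1.53, 1.34, 1.75], adjusted p = 1.58e-04, or 0.334 with an estimated correlation). Cell cycle genes were 1 higher and 40 lower of 43 (1 higher and 41 lower adjusted over the list alone, median -0.63, -0.62 at the bound [-0.71, -0.49, -0.67], adjusted p = 3.62e-18, or 0.0982 with an estimated correlation). Cholesterol synthesis genes were 20 higher and 1 lower of 23 (21 higher and 1 lower adjusted over the list alone, median 1.10 [1.02, 0.99, 1.28], adjusted p = 2.98e-11, or 0.0982 with an estimated correlation). Genes of MHC and antigen presentation were 20 higher and 0 lower of 29 (21 higher and 0 lower adjusted over the list alone, median 0.35 [0.26, 0.41, 0.32], adjusted p = 1.26e-06, or 0.201 with an estimated correlation), with a median of 0.22 after normexp correction. H2-DMa and H2-DMb1, which load peptide on class II molecules, were higher by 1.22 ± 0.07 and 1.28 ± 0.06. Stress genes were 18 higher and 3 lower of 25 (median 0.44 [0.39, 0.35, 0.55], adjusted p = 1.58e-04, or 0.108 with an estimated correlation). Chemokine genes were 11 higher and 4 lower of 19 (11 higher and 5 lower adjusted over the list alone, median 0.92 [1.07, 0.70, 0.74], adjusted p = 0.0114, or 0.474 with an estimated correlation). Neutrophil and granulocyte precursor markers were 1 higher and 10 lower of 17 (median -1.10, -0.58 at the bound [-0.21, -1.24, -1.25], adjusted p = 0.0114, or 0.434 with an estimated correlation), a call that ended with only probes detected on all arrays (median -0.71), and their median was -0.37 after normexp correction. limma called 9053 features, 5031 higher and 4022 lower, of which 1999 by at least 2-fold (9714 with the slide as a block).

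Loss of the second gene was also compared on each single-knockout background. With CpG-B, DKO cells held less interferon transcript than Lyn-KO cells: Ifnb1 was lower, at -2.23 ± 0.25, Ifna5 at -1.52 ± 0.27 and Lta at -2.75 ± 0.18, and Il10 at -2.69 ± 0.19. Cxcl2 and Cxcl3 were higher by 2.52 ± 0.35 and 2.74 ± 0.50, Srxn1 by 2.03 ± 0.11 and Hmox1 by 1.15 ± 0.20. Of the interferon genes 13 of 14 were lower (median -1.25 [-0.93, -1.35, -1.47], adjusted p = 9.58e-07, or 0.144 with an estimated correlation). Cytokine genes were 2 higher and 8 lower of 19 (median -0.27 [-0.48, -0.14, -0.35], adjusted p = 0.00173, or 0.0805 with an estimated correlation), a call that ended with only probes detected on all arrays (median -0.20). Without replicate 1 of the DKO arrays their median was -0.16, and with every probe tested on its own -0.65. Cholesterol synthesis genes were 21 higher and 1 lower of 23 (median 0.80 [0.73, 0.81, 0.89], adjusted p = 3.31e-13, or 0.0534 with an estimated correlation). Stress genes were 21 higher and 0 lower of 25 (23 higher and 0 lower adjusted over the list alone, median 0.62 [0.59, 0.47, 0.60], adjusted p = 5.99e-11, or 0.00752 with an estimated correlation). Cell cycle genes were 1 higher and 34 lower of 43 (1 higher and 37 lower adjusted over the list alone, median -0.38 [-0.50, -0.30, -0.35], adjusted p = 2.37e-13, or 0.0805 with an estimated correlation). Mast cell, basophil and eosinophil markers were 7 higher and 0 lower of 11 (8 higher and 1 lower adjusted over the list alone, median 1.08, 0.91 at the bound [0.85, 0.89, 0.77], adjusted p = 0.0175, or 0.159 with an estimated correlation), with Cpa3 and Mcpt8, proteases of these cells, at 2.04 ± 0.35 and 1.45 ± 0.26. Normexp correction gave a median of 0.49 for that list and 1.30 for Cpa3. limma called 6369 features, 3403 higher and 2966 lower, of which 984 by at least 2-fold (6884 with the slide as a block).

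Against Irf5-KO cells, DKO cells with CpG-B held more interferon transcript. Ifnb1 was higher, at 2.73 ± 0.25, Ifna4 at 2.77 ± 0.36, Tnf at 1.91 ± 0.17, Il6 at 1.20 ± 0.12 and Cxcl2 at 2.75 ± 0.35, whereas Il10 was lower, at -1.74 ± 0.19. Pou2af1 was lower, at -5.07 ± 0.37, and Ms4a1 at -1.06 ± 0.19, and Blnk was higher, at 0.83 ± 0.06. All 14 interferon genes were higher (median 2.53 [2.49, 2.76, 2.35], adjusted p = 1.29e-11, or 0.128 with an estimated correlation). Chemokine genes were 13 higher and 0 lower of 19 (13 higher and 1 lower adjusted over the list alone, median 0.86 [0.82, 0.76, 0.81], adjusted p = 1.78e-05, or 0.2 with an estimated correlation). Cell cycle genes were 1 higher and 33 lower of 43 (1 higher and 35 lower adjusted over the list alone, median -0.44 [-0.56, -0.41, -0.37], adjusted p = 1.3e-15, or 0.128 with an estimated correlation). Plasmacytoid dendritic cell markers were 11 higher and 0 lower of 18 (median 0.63 [0.39, 0.73, 0.70], adjusted p = 5.07e-06, or 0.2 with an estimated correlation), with a median of 0.37 after normexp correction. limma called 6675 features, 3656 higher and 3019 lower, of which 1123 by at least 2-fold (7345 with the slide as a block).

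The loss of each gene changed many of the same features on both backgrounds with CpG-B. For Irf5 loss, in WT and in Lyn-KO cells, 3574 features were called in the same direction, 2033 higher and 1541 lower against 491 and 328 for independent lists, and 75 in opposite directions (Pearson 0.687 and Spearman 0.605 across all features, which are not independent). For Lyn loss, in WT and in Irf5-KO cells, 3603 were called in the same direction, 1953 higher and 1650 lower against 510 and 339, and 68 in opposite directions (Pearson 0.773, Spearman 0.635). The comparisons within each pair shared no array. Without stimulation, Lyn loss called 509 features in the same direction, 160 higher and 349 lower against 9.12 and 16 for independent lists, and 5 in opposite directions. Irf5 loss called 13, 6 higher and 7 lower against 0.0539 and 0.0632, and 0 in opposite directions. There limma called 32 features in DKO against Lyn-KO. Of 20189 features, 1349 had an unadjusted p below 0.05 in that comparison, where a share of 0.05 would with no difference.

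The test of the difference between genotypes asked whether the CpG-B response itself changed. Against the WT response, the Irf5-KO response was smaller for Ifnb1 (-1.79 ± 0.35), Tnf (-1.21 ± 0.23), Il10 (-2.35 ± 0.27) and Il27 (-1.89 ± 0.22) and larger for Il1b (1.36 ± 0.20). It was also smaller for Hsd11b1 (-3.57 ± 0.24) and for Nupr1, a stress-response regulator (-3.60 ± 0.20), and larger for the cholesterol synthesis gene Sqle (0.82 ± 0.10). Il10 started higher in unstimulated Irf5-KO than in WT arrays, as given above, a call lost with only those 6 arrays fitted. Its difference thus rests partly on that higher start. Interferon genes were 0 higher and 6 lower of 14 (median -0.89, -0.88 at the bound [-0.62, -1.33, -0.66], adjusted p = 2.24e-05, or 0.403 with an estimated correlation). Cytokines were 2 higher and 8 lower of 19 (3 higher and 9 lower adjusted over the list alone, median -0.63, -0.46 at the bound [-0.68, -0.79, -0.26], adjusted p = 4.19e-05, or 0.0667 with an estimated correlation), with a median of -0.42 without replicate 1 of the unstimulated WT arrays. Cholesterol synthesis genes were 15 higher and 0 lower of 23 (18 higher and 0 lower adjusted over the list alone, median 0.68 [0.48, 0.64, 0.76], adjusted p = 6.89e-11, or 0.0667 with an estimated correlation). Glycolysis genes were 8 higher and 0 lower of 22 (12 higher and 1 lower adjusted over the list alone, median 0.40 [0.34, 0.41, 0.37], adjusted p = 8.84e-06, or 0.0667 with an estimated correlation). limma called 2555 features, 1511 with a higher and 1044 with a lower difference (2983 with the slide as a block).

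The Lyn-KO response was larger than that of WT for Ifnb1 (3.61 ± 0.35), Tnf (1.03 ± 0.23), Cxcl2 (1.98 ± 0.50) and Ifit3 (2.40 ± 0.42), and Ms4a1, which fell in WT cells (-1.81 ± 0.19), differed by 2.43 ± 0.27 and Fcmr by 4.46 ± 0.36. In unstimulated arrays Ifnb1 was above background on 1 of 3 Lyn-KO arrays, 1 of 3 DKO arrays and 2 of 3 Irf5-KO arrays, so differences of its response rest partly on signals near the background. Interferon genes were 13 higher and 0 lower of 14 (14 higher and 0 lower adjusted over the list alone, median 2.87, 2.83 at the bound [2.79, 2.63, 2.88], adjusted p = 9.14e-19, or 0.029 with an estimated correlation). Chemokine genes were 11 higher and 0 lower of 19 (13 higher and 0 lower adjusted over the list alone, median 1.06, 0.99 at the bound [0.93, 0.96, 1.17], adjusted p = 1.5e-08, or 0.108 with an estimated correlation). Interferon-stimulated genes were 22 higher and 0 lower of 61 (28 higher and 0 lower adjusted over the list alone, median 0.40 [0.51, 0.48, 0.32], adjusted p = 8.17e-10, or 0.466 with an estimated correlation). The last group, and Ifit3, Ms4a1 and Fcmr, started lower in unstimulated Lyn-KO cells, as given above. With CpG-B, Fcmr and that list were not called different from WT, and Ms4a1 was still lower. For these the difference thus does not reflect a higher level than in WT with CpG-B. limma called 2237 features, 1222 with a higher and 1015 with a lower difference (2632 with the slide as a block), and 1395 without the filter on dim probes.

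The DKO response was larger than that of WT for Cxcl2 (3.88 ± 0.50), Il1b (2.18 ± 0.20), Ifnb1 (1.86 ± 0.35), Hmgcs1 (1.03 ± 0.12) and Cd36, a scavenger receptor (3.70 ± 0.27), and smaller for Il27 (-1.12 ± 0.22), Mcm4 (-0.97 ± 0.11), Nupr1 (-4.57 ± 0.20) and Soat2, a cholesterol-esterifying enzyme (-4.63 ± 0.24). Cell cycle genes were 1 higher and 29 lower of 43 (1 higher and 33 lower adjusted over the list alone, median -0.51, -0.50 at the bound [-0.55, -0.34, -0.56], adjusted p = 3.41e-13, or 0.208 with an estimated correlation). Cholesterol synthesis genes were 18 higher and 1 lower of 23 (19 higher and 1 lower adjusted over the list alone, median 0.97 [0.78, 0.88, 1.14], adjusted p = 1.69e-09, or 0.208 with an estimated correlation). Interferon genes were 12 higher and 0 lower of 14 (median 1.64, 1.41 at the bound [2.16, 1.13, 1.57], adjusted p = 4.59e-05, or 0.363 with an estimated correlation). Interferon-stimulated genes were 31 higher and 0 lower of 61 (36 higher and 0 lower adjusted over the list alone, median 0.50 [0.75, 0.22, 0.61], adjusted p = 2.66e-06, or 0.48 with an estimated correlation). These genes also started lower in unstimulated DKO than in WT cells, as given above. Normexp correction gave a median of 0.29 for them and 1.06 for Ifnb1. With CpG-B, Ifnb1 was called higher in DKO than in WT cells only after normexp correction, as given above. limma called 6161 features, 3494 with a higher and 2667 with a lower difference (6807 with the slide as a block).

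The Irf5 dependence of the Lyn-KO effect was tested as the effect of Lyn loss on the Irf5-KO background minus its effect on the WT background. With CpG-B this difference was negative for Il10 (-1.59 ± 0.27) and positive for Il6 (0.89 ± 0.17), for Tbx21, a transcription factor gene (2.30 ± 0.22), and for Elovl6, a fatty acid elongase (1.73 ± 0.10). For Ifnb1 it was 0.01 ± 0.35 (adjusted p = 0.994). Mast cell, basophil and eosinophil markers were 4 higher and 0 lower of 11 (6 higher and 0 lower adjusted over the list alone, median 0.96 [1.95, 1.12, 0.45], adjusted p = 6.25e-06, or 0.0269 with an estimated correlation), with Mcpt8 at 2.51 ± 0.37 and Prss34, a mast cell and basophil protease, at 1.38 ± 0.22. After normexp correction the median of the list was 0.45. limma called 730 features, 332 with a higher and 398 with a lower difference (979 with the slide as a block), 351 without the filter on dim probes and 303 with only the arrays of these 4 groups. Without stimulation limma called 12 features, 6 with a higher and 6 with a lower difference. Of the 20189 features tested, 1123 had an unadjusted p below 0.05 (limma), where a share of 0.05 would with no difference. Prss34 was again positive (1.61 ± 0.22) but lost its call with only the arrays of these 4 groups fitted, and of the same marker list 2 of 11 (6 higher and 0 lower adjusted over the list alone) were called higher (median 0.96, 0.93 at the bound [0.93, 0.93, 1.02], adjusted p = 4.43e-08, or 0.00632 with an estimated correlation). The unstimulated count was 3 with only the arrays of these 4 groups, 6 with probes detected on all arrays, and 27 and 19 without replicate 3 of the unstimulated WT or DKO arrays.

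Genes near a targeted locus can carry DNA of the strain in which the allele was made, so called genes were counted around Irf5 and Lyn. With CpG-B, 48 of 125 named genes within 20 Mb of Irf5 were called in Irf5-KO against WT, or 38.4%, against 30.9% elsewhere (odds ratio 1.4, Fisher's exact test, 2-sided p = 0.0796), or 1.42 within 40 Mb (exact p = 0.017), and 56 of 125 in DKO against Lyn-KO (odds ratio 1.3, exact p = 0.166). Within 20 Mb of Lyn, 16 of 51 were called in Lyn-KO against WT (odds ratio 1.09, exact p = 0.76) and 22 of 51 in DKO against Irf5-KO (odds ratio 1.18, exact p = 0.568). Without stimulation, 6 of 51 genes near Lyn were called in Lyn-KO against WT, or 11.8%, against 4.63% elsewhere (odds ratio 2.75, exact p = 0.0303), a difference that was lost within 40 Mb (odds ratio 1.48, exact p = 0.296). In DKO against Irf5-KO, 5 of 51 were called (odds ratio 1.9, exact p = 0.199), and a window of 10 Mb gave an odds ratio of 3.13 (exact p = 0.031). None of the 8 tests within 20 Mb passed after Benjamini-Hochberg adjustment over them, the lowest adjusted p being 0.242.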

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

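The tests in this part that were chosen only after the result was seen are those of the Ifna probes, of the share of plasmacytoid dendritic cells and of array position, and so was the look at which splits kept the CpG-B groups or ran along a genotype.

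Genotypes differed in their CpG-B response by a test of the difference itself, with 3 arrays in each of the 4 groups of a test. In Irf5-KO against WT limma called 2555 features. The difference (log2) was -1.79 for Ifnb1, -1.21 for Tnf, -2.35 for Il10, -1.89 for Il27, 1.36 for Il1b, -3.57 for Hsd11b1, -3.60 for Nupr1 and 0.82 for Sqle. Il10 started higher in unstimulated Irf5-KO than in WT arrays, so its difference rests partly on that start. List medians were -0.89 for interferon genes, -0.63 for inflammatory cytokines (-0.42 without replicate 1 of the unstimulated WT arrays), 0.68 for cholesterol synthesis and 0.40 for glycolysis. None of these 4 lists was called with an estimated correlation (adjusted p = 0.403, 0.0667, 0.0667 and 0.0667). In Lyn-KO against WT 2237 features were called. The difference was 3.61 for Ifnb1, 1.03 for Tnf, 1.98 for Cxcl2, 2.40 for Ifit3, 2.43 for Ms4a1 and 4.46 for Fcmr. Ifit3, Ms4a1, Fcmr and the interferon-stimulated genes started lower in unstimulated Lyn-KO than in WT arrays. Their differences rest at least partly on that lower start. With CpG-B, Fcmr and the list of interferon-stimulated genes were not called different from WT, and Ms4a1 was still lower, as given above. For these the difference thus does not reflect a higher level than in WT with CpG-B. List medians were 2.87 for interferon genes, 1.06 for chemokines and 0.40 for interferon-stimulated genes. With an estimated correlation the interferon genes kept their call (adjusted p = 0.029), and the chemokines (adjusted p = 0.108) and the interferon-stimulated genes (adjusted p = 0.466) did not. In DKO against WT 6161 features were called, with 3.88 for Cxcl2, 3.70 for Cd36, 2.18 for Il1b, 1.86 for Ifnb1 (1.06 after normexp correction), 1.03 for Hmgcs1, -1.12 for Il27, -0.97 for Mcm4, -4.57 for Nupr1 and -4.63 for Soat2. List medians were -0.51 for cell cycle, 0.97 for cholesterol synthesis, 1.64 for interferon genes and 0.50 for interferon-stimulated genes (0.29 after normexp correction). The interferon-stimulated genes also started lower in unstimulated DKO than in WT arrays. With CpG-B, Ifnb1 was called higher in DKO than in WT arrays only after normexp correction. With an estimated correlation none of these 4 lists was called (adjusted p = 0.208, 0.208, 0.363 and 0.48).

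The effect of Lyn loss differed with the Irf5 label for 730 features with CpG-B and 12 without. With CpG-B the difference was -1.59 for Il10, 0.89 for Il6, 2.30 for Tbx21, 1.73 for Elovl6, 2.51 for Mcpt8 and 1.38 for Prss34, and without stimulation 1.61 for Prss34. The median for mast cell, basophil and eosinophil markers was 0.96 with CpG-B (0.45 after normexp correction) and 0.96 without, and with an estimated correlation both kept their call (adjusted p = 0.0269 and 0.00632). For Ifnb1 no difference was called with CpG-B (adjusted p = 0.994, limma), which does not show that there was none.

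Other splits of the same arrays, which dealt out the genotypes anew within each treatment, were fitted to see how many features they called. For the differences in Irf5-KO, Lyn-KO and DKO against WT, 3, 3 and 2 of 100 splits, the real one included, called as many as the real 2555, 2237 and 6161. That share is under 0.05, but every split that large kept the real CpG-B groups apart, the highest counts among the others being 1, 113 and 185, and the highest other splits called more than the real one, 2768, 3201 and 6940. The share thus rests on the grouping of the CpG-B arrays, takes no account of the slide, and is not read as excluding chance for a change of the response. For the Irf5 dependence of the Lyn-KO effect, 13 of 100 splits with CpG-B and 8 of 100 without called as many as the real 730 and 12, so by this count chance cannot be excluded. The highest of them called 6704 and 2120, several times the real counts, which points to a structure of the samples. With CpG-B all 12 of the other splits as large ran largely along 1 genotype, and without stimulation 6 of 7. Such splits carry the effect of that genotype, so this count decides nothing on the Irf5 dependence itself.

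Interferon genes were higher in Lyn-KO than in WT cells with CpG-B, with a median of 2.80 over 14 genes. As a list they were called by camera at the preset correlation but not with an estimated one (adjusted p = 0.0649). A larger share of plasmacytoid dendritic cells, the main producers of interferon alpha, would raise their markers alike, but without stimulation 17 such markers had a median of 0.29 (95% bootstrap interval over genes 0.16 to 0.42), so this share as the whole cause is argued against. Signal shared between the close Ifna sequences stays open for the Ifna genes: the 3 interferon genes outside that family were called higher, Ifnb1 by 2.72 ± 0.25, near the median of the list, but Ifnl3 by 0.65 ± 0.12 and Ifnk by 0.74 ± 0.19 (median of the 3 0.74), and Ifnl3 lost its call with only these 6 arrays fitted and Ifnk without replicate 3 of the WT arrays with CpG-B (0.56). Array position cannot be told apart from genotype, since each group had a fixed position, although DKO against Irf5-KO at another pair of positions gave a median of 2.53. A change of interferon transcription with loss of Lyn, which the design names, may account for the pattern and stays among the open explanations.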

How the results depend on the processing

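All alternatives in this part were chosen before the data were examined, but the genes compared were picked after their values were seen.

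Of 471 comparisons over 38 counts, targeted genes and loci, 441 gave the same call or a count within 1.5 times. Of 989 comparisons over 71 list results 986 gave the same call, all of them at the preset correlation. With an estimated correlation between genes only 15 of the 68 called list results kept their call, so most list calls rest on the preset value. Of 2238 comparisons over 171 gene results in the text 2214 gave the same call, but this cannot be read as the stability of the calls in general. Genes that lost their call on leaving out 1 array were mostly not named, after this was seen. Of 4491 called gene results that the naming rule or the lists allow, 688 (15.3%) lost their call on leaving out 1 array, against 2 of 171 (1.17%) of those named and 686 of 4320 (15.9%) of the others.

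Without the filter on dim probes fewer features were called: 74 for Irf5-KO against WT, 608 for Lyn-KO against WT, 900 for DKO against WT and 21 for DKO against Lyn-KO, all unstimulated, 1395 for the difference of the CpG-B response in Lyn-KO and 351 for the Irf5 dependence with CpG-B. With only the groups of the contrast fitted, fewer arrays inform the spread. The unstimulated counts were then 1 for Irf5-KO against WT, 321 for Lyn-KO against WT, 530 for DKO against WT and 1 for DKO against Lyn-KO, and the Irf5 dependence gave 303 with CpG-B and 3 without. This setting also ended the calls of 19 of the named gene results, of which all but Ifnl3 in Lyn-KO against WT with CpG-B were in unstimulated comparisons. DKO against Lyn-KO without stimulation gave 51 after quantile normalisation. With only probes well above background on all arrays, so fewer features tested, it gave 21, and the Irf5 dependence without stimulation gave 6. For quantile normalisation the cause was not tested.

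Leaving out 1 array moved unstimulated counts by more than 1.5 times. Irf5-KO against WT gave 53 without WT replicate 1 and 77, 46 and 97 without Irf5-KO replicates 1, 2 and 3 (up to 184, without WT replicate 3). Lyn-KO against WT gave 593 without Lyn-KO replicate 3 (up to 1064, without replicate 1). DKO against WT gave 872 without WT replicate 1 and 886 without DKO replicate 1 (up to 1455, without WT replicate 2). DKO against Lyn-KO gave 20 without Lyn-KO replicate 3 and 51 without DKO replicate 3, and DKO against Irf5-KO gave 704 without Irf5-KO replicate 2 (up to 880, without DKO replicate 3). The Irf5 dependence gave 27 without WT replicate 3 and 19 without DKO replicate 3 (down to 8, without Irf5-KO replicate 2). The cause was not tested.

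The odds ratio near the targeted genes became 1.42 within 40 Mb of Irf5 (Irf5-KO against WT, CpG-B), 1.48 within 40 Mb of Lyn (Lyn-KO against WT, unstimulated) and 3.13 within 10 Mb of Lyn (DKO against Irf5-KO, unstimulated), where the call at the unadjusted threshold changed. The cause was not tested. The share of higher calls moved from 53.1% to 66.7% after normexp for unstimulated DKO against Lyn-KO, and from 50% to 77.8% for the Irf5 dependence without stimulation. It moved from 43% to 53.8% after median scaling for unstimulated Irf5-KO against WT. Smaller moves also turned the majority of calls in large results. After quantile normalisation the share of higher calls went from 55.4% to 49.4% for Lyn-KO against WT, 55.6% to 48.3% for DKO against WT, 53.4% to 48.4% for DKO against Lyn-KO and 54.8% to 47.2% for DKO against Irf5-KO, all with CpG-B. After median scaling it went from 59.1% to 49.8%, 54.6% to 44.8% and 56.7% to 48.2% for the differences of the CpG-B response in Irf5-KO, Lyn-KO and DKO, and from 46.6% to 53.4% for unstimulated DKO against WT. The majority in these results thus depends on the scaling. Counts of at least 2-fold changes moved by more than 1.5 times in 15 of 19 contrasts after normexp, 17 with only probes well above background on all arrays and 5 with only the groups of the contrast. The offset of 50 in normexp by itself makes folds of dim genes smaller. How far it accounts for the moved counts was not tested, and dim genes were not tested apart. For the other settings the cause was not tested. Signal over background limits the folds given as lower bounds, which are set by the lowest signal well above background.

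Some called values in the text moved by more than 1.5 times, none to the other direction, and are given beside each result. After normexp these were 14 list medians and 14 gene values, all nearer 0. That setting adds an offset of 50 to each signal, which by itself draws log2 changes of dim genes toward 0. The median processed signal of an array was only 23.6 to 40.8. How far the offset accounts for each move was not tested. With every probe tested on its own, 4 list medians moved so, and with only probes detected on all arrays 3. On leaving out 1 array 7 list medians and 1 gene value did. The cause of these other moves was not tested.

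The replicate number was checked as a pairing. Same-numbered arrays of different groups had deviations correlated between -0.084 and 0.291 (median 0.0555), 25 of 84 pairs above 0.1, and 22 of 24 arrays correlated best with their own number. Unstimulated and CpG-B arrays of the same genotype and number gave 0.154, 0.143 and 0.215 in WT and 0.192, 0.146 and 0.133 in Irf5-KO. They gave 0.28, 0.138 and 0.19 in Lyn-KO and 0.261, 0.083 and 0.164 in DKO. The fit took these arrays as independent, and a block for the number does not model a link within a genotype. What links them was not tested. The labels do not say what the number marks, but each number was 1 slide, so it is also a batch that holds 1 array of every group. With the replicate number as a block the counts rose, to 14182 for CpG-B in WT, 5729 for Irf5-KO and 5796 for Lyn-KO against WT with CpG-B, and 979 for the Irf5 dependence with CpG-B, and list calls went from 192 to 194. No count moved by more than 1.5 times, and all 68 called list results in the text stayed called at the preset correlation.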

Other observations

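The tests in this part that were chosen only after the result was seen are the 2 tests of the Irf5 signal, and the interval for the B cell genes was also added after the result.

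B cell markers were lower in unstimulated Lyn-KO than in WT arrays. A second list of 12 measured B cell genes, written to test a smaller share of B lineage cells, had a median of -0.10, with 4 lower and 0 higher by limma, so it met the bound set beforehand against that share (a median above -0.5). It did not meet it by more than its spread: the 95% bootstrap interval over genes, -0.53 to 0.02, reached just past the bound. Single genes of the list ranged from -2.495 to 0.165. In unstimulated DKO against Irf5-KO arrays 5 of them were lower and 0 higher (median -0.34). Whether only B lineage cells make these genes in such cultures was not checked. Their median thus cannot decide, and the share of B lineage cells is left open. A change of transcription in B lineage cells with loss of Lyn, which the design names, was not tested.

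The Irf5 signal on the arrays labelled Irf5-KO and DKO was higher with CpG-B, by 0.64 against WT and 0.76 against Lyn-KO, while without stimulation each of these arrays lay below those of WT or Lyn-KO (-0.30 and -0.29), a difference that limma did not call (adjusted p = 0.161 and 0.347). If these arrays held RNA of the same Irf5 genotype as WT and Lyn-KO and did not differ otherwise, no excess of shared calls would be seen. In Irf5-KO against WT and DKO against Lyn-KO with CpG-B, 3574 features were called in the same direction, where independent lists give 819. The arrays thus differed in a shared way. Another steady difference between the cultures, or the fixed array positions, would also give shared calls, so this count cannot decide on the Irf5 genotype. Only 1 probe was matched to Irf5 by its accession, and the 28919 probes without a name were not searched for others. With this probe alone, whether it lies outside the deleted part of the gene cannot be told apart from a transcript that is still made.

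Genes near a targeted allele could differ because of flanking DNA from another strain. With CpG-B the odds ratios within 20 Mb were 1.4 (Irf5-KO against WT) and 1.3 (DKO against Lyn-KO) around Irf5, and 1.09 (Lyn-KO against WT) and 1.18 (DKO against Irf5-KO) around Lyn, which leaves this open.

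For each comparison of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05. The real count and the highest other were 13824 and 1 for CpG-B in WT, 13499 and 0 in Irf5-KO, 13910 and 8 in Lyn-KO and 14235 and 0 in DKO. Unstimulated they were 149 and 2 for Irf5-KO against WT, 925 and 421 for Lyn-KO against WT, 1370 and 4 for DKO against WT, 32 and 2 for DKO against Lyn-KO and 1079 and 1 for DKO against Irf5-KO. With CpG-B they were 5149 and 4, 5082 and 2, 9053 and 1, 6369 and 4, and 6675 and 2 in the same order.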
